A study of Gallus gallus with 12 samples.

How the data were processed

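RNA from the shell gland of 12 broiler breeder hens was extracted with TRIzol, and samples with an RNA integrity number above 7 were made into libraries with the NEBNext Ultra II Directional kit, which marks strand, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and DESeq2 and genome build GRCg7b, with no version or order. The counter, the annotation release and the strand setting are not given in the sources used here, so counts from the strand opposite to the transcript are neither shown nor ruled out. The deposited count table holds whole-number counts for 29558 gene identifiers, of which 19580 had a count in any library and 4624 a count in all 12. The deposited normalized table holds a signal equal to the count divided by 1 factor per library, for the same 19580 genes, and the factors equal the DESeq2 size factors computed from the counts. The authors' deposited table of differing genes gives a log2 fold change with its standard error, a score that is their ratio, a p-value and an adjusted p-value for 252 genes. Its log2 fold changes are positive where a gene is higher at 35 weeks, as seen from the counts.

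Gene names were given in the files for 144 identifiers only, all in the authors' deposited table. The RefSeq table of GRCg7b used here carries no matching identifiers, so 0 further names came from it. Of the 144 named genes 136 (94.4%) overlapped best with a RefSeq gene of the same symbol by position. Set tests of the fixed gene lists needed 5 named members and were not run, and the shares of haemoglobin and mitochondrially encoded genes were not computed, since the members were not named.

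Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 (2897 genes, 95.2% of counts), scaled by TMM, and tested with the robust quasi-likelihood F test for 50 against 35 weeks with no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and a 2-fold filter was applied after the test. CPM values were computed from the counts with TMM effective library sizes. Library properties were compared by two-sided exact permutation tests over 924 assignments. On data simulated for this comparison with 2897 genes, of which 2859 entered the fit, the test recovered 52% of genes changed 2-fold and 95% of those changed 4-fold, and 8 of 155 calls were unchanged genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.

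The rule for named genes was fixed before the data were examined. It took, among genes with a symbol, an adjusted p under 0.05 and a mean of at least 2 CPM, the 12 with the largest rise and the 12 with the largest fall, up to 4 passing members of each fixed list, and a set of shell gland genes of which CALB1, SPP1 and OTOP2 were named in the files. Alternatives fixed at the same time were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom with quality weights, 1 surrogate variable (sva 3.50.0), each hen left out in turn, an adjusted p of 0.1 and a log2 scale for library properties. Added after seeing the data were the authors' size factors, leaving out the 2 most abundant genes, the naming rule under the lighter filter, and all of these alternatives for 4 genes without a name.

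Breeder numbers were not shared between ages, so hens were not paired. The 12 libraries were separate: between hens of an age, counts differed by 4.68 to 31.1 times sampling noise in chi-square per degree of freedom. Library totals of 368000 to 652156 counts limit precision for genes of low abundance, and floors cover counting error only. The labels give no collection day or library batch, so a batch that follows age cannot be told apart from age.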

Results

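Gene counts were obtained from the shell gland, the uterine segment of the hen's oviduct where the eggshell is mineralized, of 12 broiler breeder hens. Broiler breeders are the parent stock of meat chickens. The hens were 35 weeks old, at peak egg production, or 50 weeks old, when production was declining, with 6 hens at each age, and all had an egg in the gland at sampling. The comparison asked how the gland's transcripts differed between these ages, alongside changes in shell quality. Total counts per library ranged from 368000 in hen 16 of 35 weeks to 652156 in hen 34 of 50 weeks, and 9044 to 11267 genes had a count. At this depth 1 count stood for 1.49 to 3.36 CPM (counts scaled to a common library size), so transcripts of low abundance were measured with few counts. The library kit marks strand and the strand setting of the counting is not given in the sources used here, so for every level and difference given it is open whether reads of the gene's own strand or of the opposite strand were counted.

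The largest differences between ages were losses. TM4SF19, a membrane protein of the transmembrane 4 L6 family, fell from 5250 ± 4297 CPM (SD, n = 6) at 35 weeks to 35.3 ± 29.8 CPM (SD, n = 6) at 50 weeks, a log2 fold change of -7.23 (SE 0.710, edgeR adjusted p = 0.000101). KAT2B, a histone acetyltransferase, fell from 201 ± 112 to 5.37 ± 4.19 CPM (SD, n = 6 each), a log2 fold change of -5.17 (SE 0.543, edgeR adjusted p = 0.000113). DCBLD2, a transmembrane receptor-like protein, fell from 351 ± 117 to 43.4 ± 10.4 CPM (SD, n = 6 each), with a log2 fold change of -3.01 (SE 0.266) and the smallest adjusted p of the genes tested (edgeR, 3.22e-05). In each of these 3 genes all 6 hens of 50 weeks lay below all 6 hens of 35 weeks. On build GRCg7b, the authors' deposited table places TM4SF19 (ENSGALG00010024844) on chromosome 9 from 4405586 to 4417994. It places KAT2B (ENSGALG00010001778) on chromosome 2 from 35754170 to 35793926, and DCBLD2 (ENSGALG00010005490) on chromosome 1 from 84788903 to 84831364.

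Of 2897 genes tested, 78 were higher and 97 lower at 50 weeks at an adjusted p under 0.05 (edgeR quasi-likelihood test), and 102 of these 175 differed at least 2-fold, 42 upward and 60 downward. Of the 175 genes, 13 carried a name in the files, 10 of them lower and 3 higher at 50 weeks. All 13 names came from the authors' deposited table of differing genes, so the named genes are a selection made on these same hens, and the other 162 are known here by identifier alone. The numbers of calls fell by more than 1.5 times when single hens were left out. Without hen 30 of 35 weeks 44 genes were higher, without hens 32, 33 and 34 of 50 weeks 50, 46 and 51 were higher, and without hen 29 of 35 weeks or hen 33 of 50 weeks 63 and 64 were lower.

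**Figure D1:**
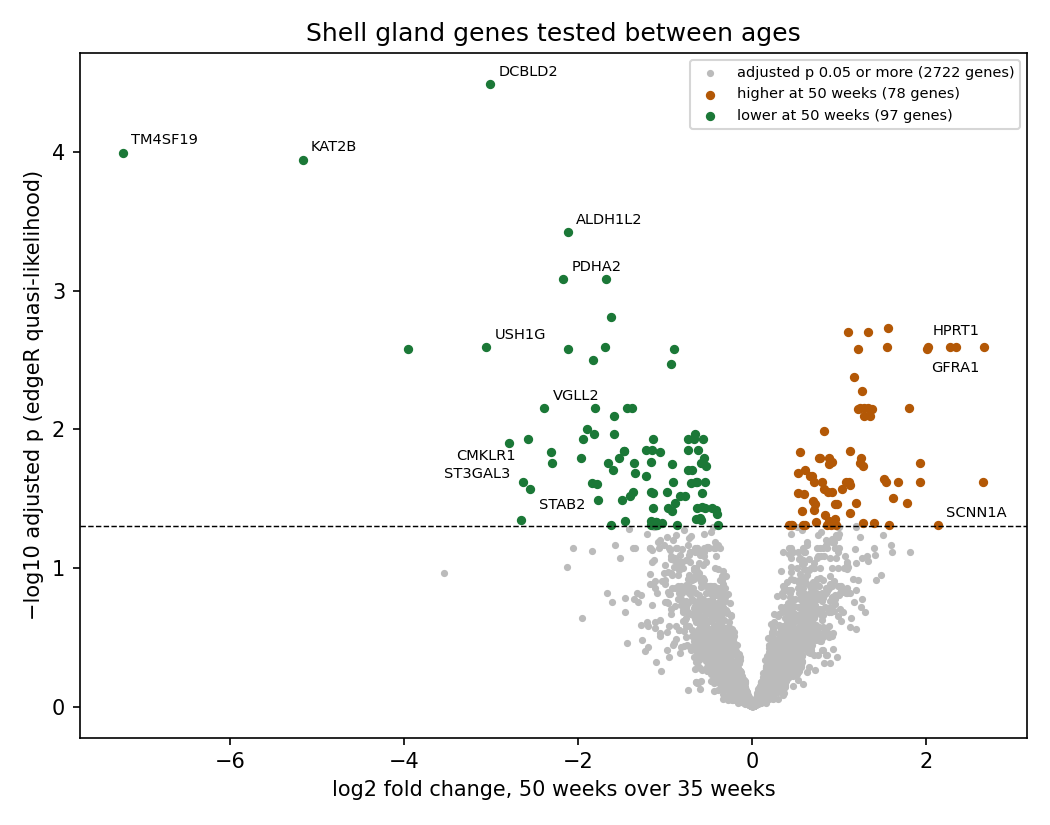
Each point is 1 of the 2897 genes tested, with the log2 fold change of 50 over 35 weeks on the x axis and −log10 of the edgeR adjusted p on the y axis; the dashed line marks an adjusted p of 0.05 and the 13 named genes past it are labelled. TM4SF19 and KAT2B lie farthest to the left, at -7.23 and -5.17.

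Several further named genes were lower at 50 weeks. PDHA2, a subunit of the pyruvate dehydrogenase complex, fell by 2.17 on the log2 scale, from 153 ± 44.2 to 33.8 ± 12.7 CPM (SD, n = 6 each, edgeR adjusted p = 0.000827). ALDH1L2, the mitochondrial 10-formyltetrahydrofolate dehydrogenase, fell by 2.12, from 685 ± 285 to 158 ± 19.2 CPM (SD, n = 6 each, edgeR adjusted p = 0.000375). VGLL2, a cofactor of TEAD transcription factors, fell by 2.39 (edgeR adjusted p = 0.00707). USH1G, a scaffold protein known from the sensory hair cell, fell by 3.06 (edgeR adjusted p = 0.00255). CMKLR1, the receptor of the chemoattractant chemerin, fell by 2.58 (edgeR adjusted p = 0.0118). In these 5 genes, too, all 6 hens of 50 weeks lay below all 6 of 35 weeks. The gap was narrowest for USH1G, from 198 CPM (59 counts) at 35 weeks to 189 CPM (103 counts) at 50 weeks, within counting error. For PDHA2 the nearest hens of 35 and 50 weeks held 24 and 27 counts, and for VGLL2 30 and 19. ST3GAL3, a sialyltransferase, fell by 2.64 (edgeR adjusted p = 0.0239) and STAB2, a scavenger receptor of sinusoidal endothelium, by 2.55 (edgeR adjusted p = 0.0267), with 2 and 5 of 6 hens of 50 weeks below all hens of 35 weeks. The calls of CMKLR1, ST3GAL3 and STAB2 were lost when 9904 genes were tested under a lighter filter, with adjusted p of 0.0630, 0.108 and 0.130. Without hen 2 of 35 weeks CMKLR1 fell by 1.95, and without hen 39 of 50 weeks USH1G fell by 3.65. STAB2 stood at -1.82 without hen 29 of 35 weeks and at -2.53 without hen 30, where its call was lost (adjusted p of 0.0607 and 0.0514), and at -3.19 without hen 42 of 50 weeks.

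The 3 named genes that rose had fold changes near 4. All names come from the authors' deposited table, whose smallest absolute log2 fold change was 2.00, so genes with smaller rises carry no name. HPRT1, the purine salvage enzyme, rose from 38.0 ± 16.2 to 154 ± 46.3 CPM (SD, n = 6 each), a log2 fold change of 2.02 (SE 0.309, edgeR adjusted p = 0.00255). GFRA1, a receptor for glial cell line-derived neurotrophic factor, rose from 15.5 ± 5.64 to 62.9 ± 23.3 CPM (SD, n = 6 each), a log2 fold change of 2.01 (SE 0.325, edgeR adjusted p = 0.00262). In both, all 6 hens of 50 weeks lay above all 6 of 35 weeks. The nearest hens of 35 and 50 weeks held few counts, 27 and 42 for HPRT1 and 10 and 19 for GFRA1. SCNN1A, the alpha subunit of the epithelial sodium channel, was the most abundant of these genes at 815 ± 784 CPM (SD, n = 6) at 35 weeks and 3550 ± 1659 CPM (SD, n = 6) at 50 weeks. Its log2 fold change of 2.13 (SE 0.588) was close to the threshold (edgeR adjusted p = 0.0492) and 5 of 6 hens of 50 weeks lay above all hens of 35 weeks. The SCNN1A call was lost in 14 of 21 alternatives, with an adjusted p of up to 0.257, and without hen 16 of 35 weeks its log2 fold change was 2.73. The authors' deposited table places SCNN1A (ENSGALG00010021866) on chromosome 1 from 76851457 to 76859672 and HPRT1 (ENSGALG00010015742) on chromosome 4 from 3982505 to 4000201.

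Of the shell gland genes fixed for naming, CALB1, SPP1 and OTOP2 were named in the files. At 35 weeks they stood at percentiles 89.2, 92.3 and 91.2 of the 19580 genes with a count in any library. That left 2109, 1516 and 1731 genes above them. Many of the 19580 had few counts, and 2897 had enough to pass the main filter, so these percentiles do not show high abundance among well-measured genes. CALB1, the calcium-binding protein calbindin, stood at 42.9 ± 33.2 CPM at 35 weeks and 10.1 ± 15.1 CPM at 50 weeks (SD, n = 6 each). Its log2 fold change of -2.13 (SE 0.727) did not pass (edgeR adjusted p = 0.0980). CALB1 also did not pass in 18 of 21 alternatives, among them the lighter filter (edgeR adjusted p = 0.266) and DESeq2 (adjusted p = 0.0661). It passed in 3. Without hen 44 of 50 weeks it stood at -3.31 (edgeR adjusted p = 0.0143). The adjusted p was 0.000747 with edgeR and no filter, and 0.0437 with limma-voom. With no filter the log2 fold change was almost the same, -2.11, but the unadjusted edgeR p was 3.86e-06 against 0.0107 with the main filter. That pass therefore reflects the filter and not a larger difference. SPP1, the matrix phosphoprotein osteopontin, and OTOP2, a proton channel, did not pass the filter used for the counts above. Under the lighter filter, of at least 1 CPM in at least 6 libraries, SPP1 fell from 79.2 ± 41.7 to 2.64 ± 3.51 CPM (SD, n = 6 each), a log2 fold change of -4.83 (SE 0.602, edgeR adjusted p = 6.95e-05). This rested on 194 counts over the hens of 35 weeks and 8 over those of 50 weeks, and without hen 44 of 50 weeks the log2 fold change was -5.52. OTOP2 fell from 64.0 ± 45.7 to 6.54 ± 4.41 CPM (SD, n = 6 each), a log2 fold change of -3.30 (SE 0.531, edgeR adjusted p = 0.000841), on 163 and 20 counts. In both genes all 6 hens of 50 weeks lay below all 6 of 35 weeks, but the gap was within counting error. For SPP1 the lowest hen of 35 weeks had 19.4 CPM from 8 counts, and the highest of 50 weeks 8.87 CPM from 4 counts. For OTOP2 the lowest hen of 35 weeks had 13.5 CPM from 4 counts, and the highest of 50 weeks 12.8 CPM from 7 counts. The authors' deposited table places SPP1 (ENSGALG00010003220) on chromosome 4 from 45233954 to 45237015, OTOP2 (ENSGALG00010029679) on chromosome 18 from 11183511 to 11190420 and CALB1 (ENSGALG00010012850) on chromosome 2 from 124001747 to 124020030. The USH1G interval in the RefSeq annotation, from 11171795 to 11191800, spans OTOP2. In the authors' deposited table the intervals of these genes lie 2069 bp apart. The annotation release used for counting is not given, so whether reads of either gene were given to the other is uncertain.

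**Figure D2:**
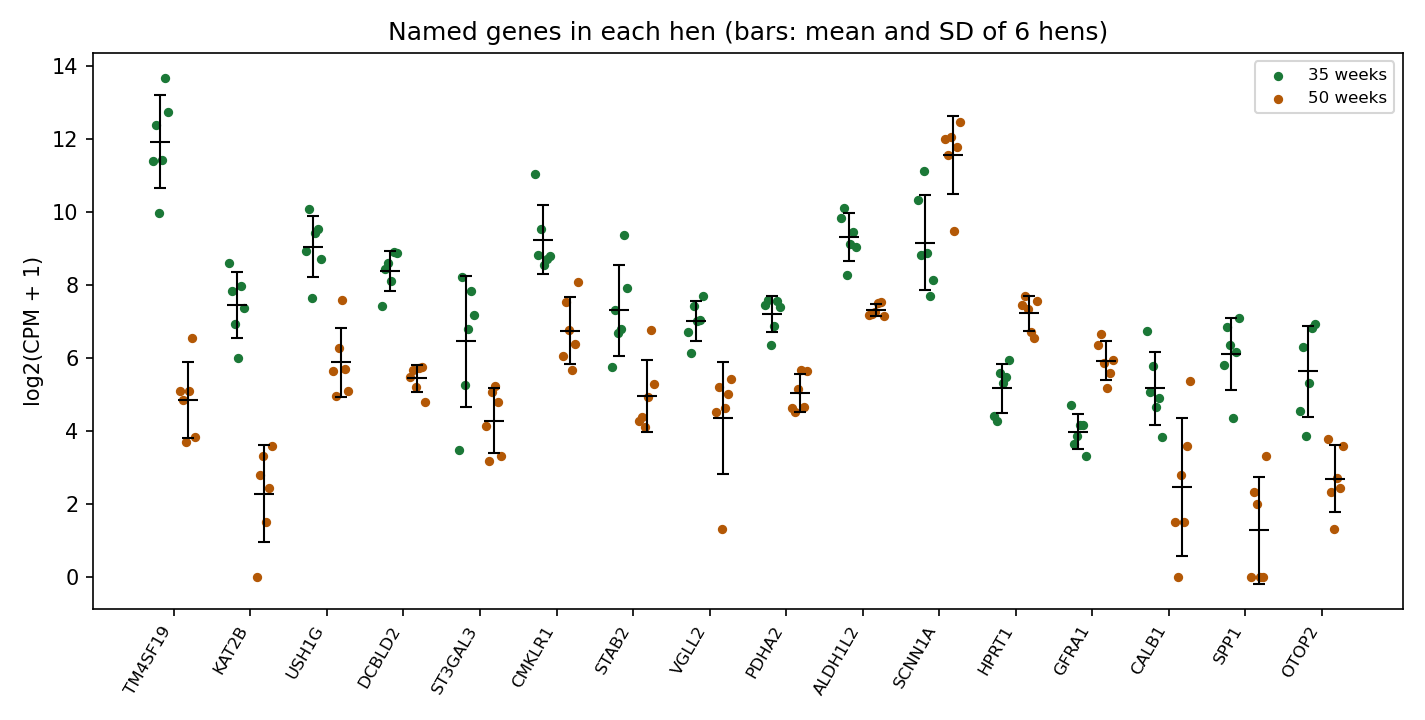
Points are log2(CPM + 1) of each hen for the 13 named genes past the threshold and for CALB1, SPP1 and OTOP2, with hens of 35 weeks in green and of 50 weeks in orange; bars give the mean and SD of the 6 hens. All 6 hens of 50 weeks lie below all 6 of 35 weeks for TM4SF19, KAT2B and, by gaps within counting error, SPP1 and OTOP2.

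The rule for naming genes was applied again under the lighter filter, a step chosen after the data were seen, and reached genes of lower abundance. There 86 genes were higher and 121 lower at 50 weeks, and 46 of them had names, 30 lower and 16 higher. NPTN, which encodes neuroplastin, a partner of the plasma membrane calcium pump, fell by 3.41 on the log2 scale (edgeR adjusted p = 0.00654). PKD2, a calcium-permeable channel, fell by 3.17 (edgeR adjusted p = 0.00102). SEPTIN3, a cytoskeletal GTPase, fell by 4.20 (edgeR adjusted p = 0.000175), ARVCF, a catenin of cell junctions, by 3.66 (edgeR adjusted p = 0.000420), and WNT11, a secreted Wnt ligand, by 3.03 (edgeR adjusted p = 0.0273). WNT11 had 17 counts at 35 weeks and 2 at 50 weeks, a ratio of 11.2 with an exact 95% counting interval of 2.66 to 99.9. Hens 34 and 44 of 50 weeks held 1 WNT11 count each, and the ratio was 17.6 (interval 2.76 to 737) without hen 34 and 19.2 (interval 3.01 to 802) without hen 44. SMIM45, a small membrane protein, had 32 and 3 counts, a ratio of 14.0 with an interval of 4.39 to 71.7 (edgeR adjusted p = 0.00934). Without hen 44 of 50 weeks, which held 2 of those 3 counts, the SMIM45 ratio was 36.1 (interval 6.04 to 1471). Among genes that rose were XIRP1, an actin-binding protein of striated muscle, at 4.10 (edgeR adjusted p = 0.000128), ETNK2, an ethanolamine kinase, at 3.34 (edgeR adjusted p = 0.000393), CLP1, an RNA kinase, at 2.09 (edgeR adjusted p = 0.0142), and CLNS1A, an assembly factor of the splicing machinery, at 2.04 (edgeR adjusted p = 0.00303). The identifier named XIRP1 in the files overlaps best with a RefSeq lncRNA, over 75.9% of their joint length, and RefSeq places XIRP1 best on another, overlapping identifier, so which transcript the counts come from is uncertain. HEYL, a target of Notch signalling, had no count in the 6 libraries of 35 weeks and 26 counts in those of 50 weeks, at least 6.58-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00419). NXNL2 had 3 and 44 counts, a ratio of 11.1 (interval 3.57 to 56.1), and LCORL 1 and 19 counts, a ratio of 14.4 (interval 2.29 to 599.7), with edgeR adjusted p of 0.0114 and 0.0478. Hen 27 of 35 weeks held all 3 counts of NXNL2 at that age and hen 29 the 1 count of LCORL, and without that hen they were at least 9.24-fold and at least 3.98-fold higher against a floor of 3 counts over the group. PLA2G15, NELFA, HS3ST3B1 and TAPBPL also rose, with log2 fold changes of 2.29 to 2.95 and adjusted p of 0.0122 to 0.0383 (edgeR), and without hen 30 of 35 weeks the value for PLA2G15 was 3.77. The identifier named HS3ST3B1 in the files overlaps best with RefSeq's HS3ST3A1, over 95.9% of their joint length, so which of these related genes it is remains uncertain. The call was lost in 13 of 19 alternatives for LCORL, 9 of 20 for PLA2G15, 8 of 20 for NELFA and 5 of 19 for WNT11, with adjusted p of up to 0.105, 0.0997, 0.0664 and 0.0707. It was lost in 3 of 20 for HS3ST3B1, with adjusted p of up to 0.0589, and in 1 of 20 for TAPBPL, with limma-voom (adjusted p = 0.0980). PKD2 lies 220 bp from SPP1, SMIM45 1148 bp from SEPTIN3, NELFA 3305 bp from ENSGALG00010018617 and TAPBPL 13602 bp from SCNN1A. Both genes of each pair changed in the same direction, and whether reads of either were given to the other is uncertain.

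Of the 34 gene lists fixed before the data were examined, 11 had a member named in the files and none had more than 2, so no list could be tested as a set. The 13 different named members were picked by the authors on these hens and are not independent evidence for any list. Of the 12 members measured under the lighter filter, 5 passed over all genes tested and 12 passed when adjusted over these members alone, pooled across lists. The second count adds no support, since it adjusts genes that the authors had already picked on these hens. Those past over all genes were SPP1 of the eggshell matrix list, OTOP2 of the bicarbonate and pH list, WNT11 of the hormone signalling list and ELOVL5, a fatty acid elongase of the lipid list, all lower at 50 weeks, and TAPBPL of the antigen presentation list, which was higher but lost its call with limma-voom (adjusted p = 0.0980). ELOVL5, at a log2 fold change of -2.65 (edgeR adjusted p = 0.0342), lost its call in 8 of 20 alternatives, each leaving out 1 hen, with adjusted p of up to 0.150 without hen 2 of 35 weeks (-2.08), and without hen 44 of 50 weeks it stood at -3.33. GPC4, HPGD, EGR3, CXCL14, CALB1, SCNN1A and STAB2 did not pass there over all genes, with adjusted p of 0.0719 to 0.276. The remaining member, CRELD2, was too low for either filter, with 10 counts at 35 weeks and 0 at 50 weeks.

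Among genes with no name in the files, 2 that rose and 2 that fell are given, chosen after their values were seen. ENSGALG00010029272 rose from 36.2 ± 25.3 to 225 ± 86.2 CPM and ENSGALG00010019496 from 74.1 ± 40.5 to 354 ± 156 CPM (SD, n = 6 each, edgeR adjusted p = 0.00255 for both). ENSGALG00010019496 lies 553 bp from HPRT1, which also rose, so the 2 may not be separate results. ENSGALG00010019292 fell from 277 ± 294 to 17.6 ± 6.32 CPM (SD, n = 6 each, edgeR adjusted p = 0.00262). Its log2 fold change was -3.96, and -3.19 without hen 2 of 35 weeks (adjusted p = 0.00215), which had 856 CPM. ENSGALG00010015233 fell from 241 ± 242 to 37.4 ± 39.2 CPM (SD, n = 6 each, edgeR adjusted p = 0.0454), a log2 fold change of -2.66. Its call was lost in 11 of 21 alternatives, 9 of which left out 1 hen, with an adjusted p of 0.192 under the lighter filter and up to 0.268 with no filter. Without hen 2 of 35 weeks, which had 723 CPM, it stood at -1.94 (adjusted p = 0.0787), and without hen 34 of 50 weeks at -3.35 (adjusted p = 0.0241). ENSGALG00010015233 lies on chromosome 20 from 10639563 to 10644212, an interval that overlaps RefSeq's BPIFB2 over 99.9% of their joint length, though the files do not give it that name.

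The libraries themselves also differed with age. Total counts were 441768 ± 43205 (SD, n = 6) at 35 weeks and 525628 ± 72102 (SD, n = 6) at 50 weeks (two-sided exact permutation test, p = 0.0260, adjusted p = 0.0260 over 3 comparisons). Genes with a count numbered 9960.5 ± 597 and 10754 ± 467 (SD, n = 6 each, exact permutation p = 0.0260, adjusted p = 0.0260). The 10 most abundant genes took 24.6 ± 2.52% of counts at 35 weeks and 20.7 ± 1.58% at 50 weeks (SD, n = 6 each, exact permutation p = 0.0130, adjusted p = 0.0260). The first principal component of log2 CPM held 27.7% of the variance.

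The authors' deposited table lists 252 genes, 149 higher at 35 weeks and 103 higher at 50 weeks, all with an absolute log2 fold change above 2. Its adjusted p was under 0.05 for 82 genes, 0.05 or more for 35 and not given for 135. Of the 25 listed genes that passed the filter here, 23 passed the edgeR test in the same direction, and under the lighter filter 78 of 223 did. DESeq2 applied to the counts gave the same 82 genes among 307 past an adjusted p of 0.05. These 82 were all of the 307 with an absolute log2 fold change of 2 or more. The other 225 fell below that size, which every listed gene exceeds. All 252 listed genes had their listed direction in the mean CPM. DESeq2 on these counts gave the listed log2 fold changes to within 4.28e-06, so agreement in direction is no independent check.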

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

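All groups of 6 hens were screened for a hen far from the others, and 11 of 82 groups had one. Chance gives about 1 in 20 for normally spread values, which skewed CPM values of few counts are not, so no excess over chance is read from this. The test of depth was chosen after the counts had been seen.

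Gaps are given as a share of the group's range. At 35 weeks hen 2 had 2092 CPM of CMKLR1 against 374 to 743 CPM in the others (gap 0.785). It was also highest at 35 weeks in ELOVL5, at 35.0 CPM from 14 counts (gap 0.627), ENSGALG00010019292, at 856 CPM (gap 0.746), and ENSGALG00010015233, at 723 CPM (gap 0.788). Hen 29 of 35 weeks had 659 CPM of STAB2 against a median of 109 CPM (gap 0.687), and without it the STAB2 adjusted p was 0.0607. Hen 42 of 50 weeks was highest in both STAB2, at 109 CPM (gap 0.768), and TM4SF19, at 93.0 CPM (gap 0.739). Hen 39 of 50 weeks had 189 CPM of USH1G (gap 0.711). Hen 44 of 50 weeks had 39.9 CPM of CALB1 from 18 counts, against 0 to 11.1 CPM in the others (gap 0.723). NXNL2 in hen 27 of 35 weeks and LCORL in hen 29 of 35 weeks stood alone above 0 with 3 counts and 1 count (gap 1 in both), where the gap follows from the zeros in the other hens. Without hen 27 NXNL2 was at least 9.24-fold higher at 50 weeks, and without hen 29 LCORL at least 3.98-fold, against a floor of 3 counts over the group.

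TM4SF19 and KAT2B were far lower at 50 weeks in every hen. Lower depth at 50 weeks is excluded, since mean total counts were higher there by 83860 (525628 against 441768, two-sided exact permutation test, adjusted p = 0.0260). Age stays open and untested as a cause, because the labels give no flock, day or batch, and these could follow age.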

How the results depend on the processing

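In the alternatives where they were tested, none of the 175 called genes reversed direction. Genes higher at 50 weeks numbered 78, and 143 with no filter, 139 with DESeq2, 121 with limma-voom and 153 at an adjusted p of 0.1. Genes lower numbered 97, and 182 with no filter, 168 with DESeq2 and 176 at an adjusted p of 0.1. Genes past 2-fold numbered 102, and 241 with no filter, 162 with at least 1 CPM in 6 libraries and 199 with DESeq2. The fit with no filter tested more genes, 19580. DESeq2 gave a p-value for 19564 genes but an adjusted p for only part of them, so fewer entered its adjustment. The cause of the differing numbers was not tested. Leaving out each hen in turn gave 44 to 88 higher, 63 to 123 lower and 81 to 124 past 2-fold, with the fewest higher without hen 30 of 35 weeks and the fewest lower without hen 29 of 35 weeks. Of the authors' listed genes 23 of the 25 in the edgeR fit passed, and 78 of 223 with edgeR under the lighter filter. With DESeq2 82 of 252 passed, and part of the 252 had no adjusted p. These counts differ in filter as well as tool. The authors' size factors gave 73 higher and 95 lower, and leaving out the 2 most abundant genes 82 and 93, both chosen after seeing the data. Among 769 alternatives for the genes given one by one, 678 kept their side of the threshold, 88 lost a call, 3 gained one and 0 reversed. SCNN1A lost its call in 14, LCORL in 13, ENSGALG00010015233 in 11, PLA2G15 in 9, STAB2, NELFA and ELOVL5 in 8, ST3GAL3 in 6, WNT11 in 5, HS3ST3B1 in 3, CMKLR1 in 2 and TAPBPL in 1; CALB1 gained one in 3. The library differences passed on the log2 scale too. Leaving out haemoglobin and mitochondrially encoded genes, and the set tests, were not run, since the files do not name those genes. No paired analysis was possible because the ages share no breeder numbers. Totals of 368000 to 652156 counts limit what can be detected in genes of few counts.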

Other observations

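The tests of neighbouring genes were chosen after the patterns had been seen, and the criterion for the splits of the hens was written down after their counts had been seen.

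The real ages gave 175 genes past an adjusted p of 0.05 and 102 past 2-fold. Of 100 splits of the 12 libraries into 6 and 6, drawn from 462, only the real split (1 of 100) gave as many in either count, and the highest of the others was 1 gene. Chance in how hens were grouped is excluded at this size; a difference in flock or day that follows age is not.

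Neighbouring genes of the authors' deposited table mostly had the same direction, whether or not each passed a test here. Of 18 pairs of consecutive listed genes within 20 kb, 17 had the same direction, 9 lower and 8 higher at 50 weeks. They include PKD2 and SPP1, 220 bp apart, USH1G and OTOP2, 2069 bp apart, SEPTIN3 and SMIM45, 1148 bp apart, DECR1 and CALB1, 4443 bp apart, and TAPBPL and SCNN1A, 13602 bp apart. They also include pairs that overlap in position and so could share reads: ENSGALG00010026666 with XIRP1, and ENSGALG00010029074 with ENSGALG00010029071. Directions shuffled over the 252 genes gave 9.26 such pairs on average (100000 shuffles, permutation p = 0.00013). Random sets of 252 RefSeq genes held 4.68 pairs within 20 kb on average and at most 15 (permutation p = 0.0001, the smallest that 10000 sets can give), although these sets were drawn from annotated protein-coding and lncRNA genes and not from those expressed in the gland. A candidate explanation is that reads of 1 strong transcript run into its neighbour in a fixed share. The ratio of both counts varied beyond counting error in 5 of 14 testable pairs, fewer than the 7 taken as the bound for excluding it. Among these were USH1G and OTOP2 (chi-square per degree of freedom 7.94, adjusted Monte Carlo permutation p = 0.0007) and DECR1 and CALB1 (2.53, adjusted p = 0.00532). HPRT1 and ENSGALG00010019496, 553 bp apart, also varied in ratio (2.76, adjusted p = 0.00525). In the other 9 pairs no difference in ratio was detected. They include PKD2 and SPP1 (adjusted Monte Carlo permutation p = 0.0583), TAPBPL and SCNN1A (0.114), SEPTIN3 and SMIM45 (0.149), and NELFA with ENSGALG00010018617 (0.114). The test allows for counting error alone, and no repeat library shows how far a fixed share would vary. A fixed share and shared regulation, which was not tested, therefore cannot be told apart. Counting of reads from the opposite strand was not tested as a cause either.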
